A study of Homo sapiens with 15 samples.

How the data were processed

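RNA levels were measured on Affymetrix expression arrays in 2 human ovarian cancer cell lines. A2780 is sensitive to cisplatin, and CP70 is a cisplatin-resistant derivative of it. Per the labels' protocols, CP70 was left untreated, given decitabine (0.1 µM for 48 h), given PXD101 (0.1 µM for 48 h), or given decitabine for 48 h with PXD101 for 24 h, and treated cells were harvested 96 h after the drugs were removed. Decitabine is a nucleoside analog that traps DNA methyltransferases. PXD101, also called belinostat, inhibits histone deacetylases. The length of exposure to PXD101 therefore differed between the arm with PXD101 alone and the combined arm. RNA was extracted with RNeasy columns (Qiagen), amplified with the WT-Ovation Pico system (NuGEN) and biotin-labelled, per the labels' protocols. The series' design text states biological triplicates, which gave 15 arrays in 5 groups of 3; replicate numbers came from the sample titles.

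The authors deposited 1 table with a log2 value for each of 54675 probe sets on each array. R 2.10.1 and the affy package are named in the submitters' processing notes. The background correction, the normalization and the summarization of probes are not given in the sources used here. The log2 scale was read from the values, which ran from about 2.4 to 14.5 with array medians of 5.00 to 5.06. After sorting, the value of an array exceeded the mean of the 15 arrays at the same rank by at most 0.108 log2. The arrays thus had nearly but not exactly the same distribution. Arrays give no counts and no depth, and the number of arrays limits the precision.

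Gene names came from the platform's annotation, updated through Entrez IDs to the symbols of the RefSeq gene table. Of all probe sets, 41097 had 1 symbol, 1801 had several and 11777 had none in the table used here. Entrez IDs matched 41043 of the single-symbol probe sets, and 54 kept the symbol of the annotation. The 62 control probe sets were left out. Each gene was represented by its probe set with the highest mean over the 15 arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. No genome was used and no coordinates are given.

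Each comparison was fitted with limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) on the deposited log2 values of all 15 arrays with group means only, so that the 5 groups shared 1 estimate of spread per gene. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 19775 genes. Changes are differences of group means on the log2 scale with their standard errors (SE), and levels are means over 3 arrays with the SD. Rank product, the test named in the design text, was computed for the 4 contrasts against an untreated line from 9 pairwise array differences with 100 permutations, at a percentage of false positives under 5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). A non-additive response was the change with both drugs minus the changes with each drug.

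Named genes were the 8 largest rises and 8 largest falls of each of the first 4 contrasts among called genes whose arrays did not overlap between the groups, up to 4 members of each described list with the smallest p, and the 10 genes with the largest product of changes in each overlap with the line contrast. For the other contrasts they were the 5 largest rises and falls, and the drug targets DNMT1, DNMT3A, DNMT3B, HDAC1, HDAC2 and HDAC3 were always reported. Genes without a single symbol were left out.

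Counts were taken over 24 gene lists with 740 genes, of which 91 had no probe set named in the table used here and were not analysed. The lists were cancer-testis antigens, germline genes outside the X-linked antigen families, interferon-stimulated genes, antigen presentation, imprinted genes, clustered protocadherins, DNA methylation machinery, histone deacetylases, genes commonly raised by histone deacetylase inhibitors, p53 targets, cell cycle and mitosis, platinum transport and thiol detoxification, metallothioneins, DNA mismatch repair, nucleotide excision and crosslink repair, apoptosis regulators, extracellular matrix and mesenchymal state, cytokines and NF-kB targets, the unfolded protein and integrated stress response, sterol biosynthesis, genes listed as methylation targets from memory of the study's published work, and markers of leukocytes, of fibroblasts and endothelium, and of keratins and squamous cells. The methylation targets were chosen at least in part on these samples. List shifts were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists.

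The samples, comparisons, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined. These alternatives were fits of only the arrays compared, a block for the replicate number, genes above the median level, the mean of all probe sets of a gene, every probe set, array weights, a minimum change of 2-fold, repeated quantile normalization, median centring and leaving out each array. Alternatives without CP70 replicates 1 and 3, or with the PXD101 arrays in place of the untreated CP70 arrays, were added after the data were seen. In simulated data for decitabine against untreated CP70 over 19775 genes, limma recovered 93.0% of genes changed by 1 log2 unit and 99.0% of those changed by 2, with 9 unchanged genes called. In a separate simulation of only these 2 groups, rank product recovered 99.0% and 100% of such genes, with 29 unchanged genes called. Its false calls were thus more than the 5% of calls that its threshold allows. The simulated noise was drawn independently for each gene and array, with 1 SD per gene pooled over the groups. It left out the departure of CP70 replicate 2 from replicates 1 and 3, so these figures need not hold for the real contrasts. No pair of arrays held identical values, and the highest correlation within a group was 0.997.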

Results

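The 15 arrays covered A2780, untreated CP70, and CP70 after decitabine, PXD101 or both drugs, with 3 biological replicates each. Array medians lay between 5.00 and 5.06 log2. Correlations across genes within a group were 0.995 to 0.997 in A2780, 0.993 to 0.997 with decitabine, 0.994 to 0.997 with PXD101 and 0.995 to 0.997 with both drugs, but reached down to 0.983 in untreated CP70. There, replicate 2 correlated at 0.995 to 0.997 with the 3 PXD101 arrays and at 0.983 and 0.986 with CP70 replicates 1 and 3. As a sign of RNA quality, the 3' actin probe set lay above the 5' one by 0.859, 0.629 and 0.647 log2 in untreated CP70 and by 0.384, 0.509 and 0.480 with PXD101. The same difference was 0.359, 0.377 and 0.337 in A2780, 0.424, 0.471 and 0.491 with both drugs, and 0.443, 0.342 and 0.787 with decitabine, the last in replicate 3. This sign thus moved with the contrasts of untreated CP70 with A2780, with PXD101 and with both drugs. In the plot of principal components, the first component, with 59.2% of the variance, parted A2780 from all CP70 arrays.

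**Figure D1:**
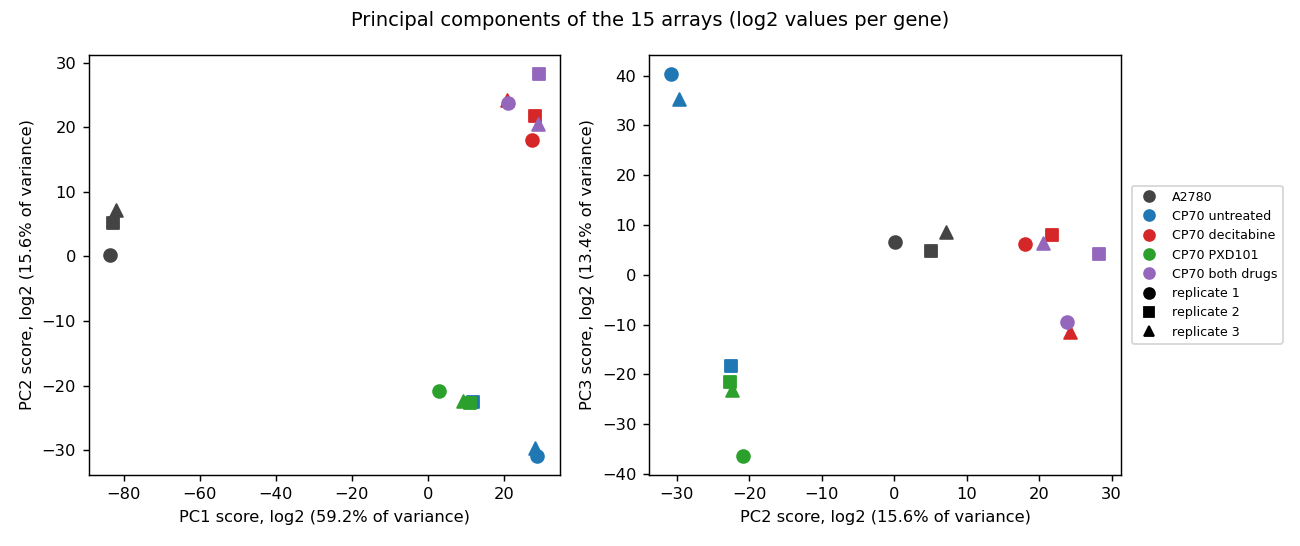
Scores of the 15 arrays on principal components 1 to 3 in log2 units, with colours for the 5 groups and circle, square and triangle for replicates 1, 2 and 3. The components hold 59.2%, 15.6% and 13.4% of the variance, and the square of untreated CP70 lies among the PXD101 arrays.

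The comparison of CP70 with A2780 asked which genes differ between the resistant line and its sensitive parent. MEST, an imprinted gene of the paternal allele, was at 13.29 log2 in A2780 and 4.16 in untreated CP70, a fall of 561-fold (-9.13 ± 0.15, SE). FABP4, a fatty acid binding protein of adipocytes, fell by 8.56 ± 0.13, and LIN28A, which blocks maturation of let-7 microRNAs, fell by 7.27 ± 0.14. NRK, PMP2, DLX6-AS1, BEX1 and MAB21L2 changed by -8.33, -8.21, -7.78, -7.30 and -7.01. XCL1, a chemokine, rose by 7.91 ± 0.17, ADAMTS5, a protease of cartilage aggrecan, by 7.52 ± 0.23, and SCG2, a granin of secretory vesicles, by 7.04 ± 0.31. The other large rises were ZPLD1 at 7.85, NIBAN1 at 6.95, DCLK1 at 6.89, SEMA6D at 6.84 and MECOM, a zinc finger transcription factor, at 6.83. Levels below the lower quartile of all gene values (4.34 log2), such as that of MEST in CP70, lie near the low end of the scale, where folds can be understated. Among thiol and platinum genes, 15 of 38 rose and 14 fell (16 and 14 adjusted over the list alone). The cystine transporter SLC7A11 rose by 5.69 ± 0.40 and the glutathione synthesis enzyme GCLC by 1.27 ± 0.10, while the glutathione peroxidase GPX1 fell by 6.37 ± 0.16, or 82.8-fold.

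Of 31 p53 target genes, 17 fell and 4 rose (18 and 6 adjusted over the list alone; camera adjusted p = 0.00312, and adjusted p = 0.680 with an estimated correlation). The falls included the apoptosis effector BAX (-1.55 ± 0.13), TP53INP1 (-2.17 ± 0.18) and TIGAR (-1.38 ± 0.11). PHLDA3, an inhibitor of AKT signalling, rose by 3.73 ± 0.14, and PMAIP1, also on this list, by 4.31. The list median was 9.485, 9.586 and 9.8 log2 in A2780 and 9.483, 9.104 and 9.727 in CP70, so that CP70 replicate 3 lay within the A2780 range. Imprinted genes fell in 12 of 33 cases and rose in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00828, and adjusted p = 0.218 with an estimated correlation). Among those that fell were DIRAS3 (-2.67 ± 0.35), FAM50B (-2.08 ± 0.16) and the homeobox gene DLX5 (-6.54 ± 0.16). For antigen presentation 9 of 30 genes fell and 1 rose, with the same numbers adjusted over the list alone, and the camera adjusted p was 0.0260 (adjusted p = 0.844 with an estimated correlation). The list median was 7.46, 8.38 and 8.60 log2 in A2780 and 7.12, 7.72 and 7.21 in CP70, so that A2780 replicate 1 lay within the CP70 range. The genes that fell included the class II chain HLA-DPA1 (-1.97 ± 0.29), the class I regulator NLRC5 (-1.89 ± 0.32) and the immunoproteasome subunit PSMB9 (-2.65 ± 0.44, with an SD of 1.25 log2 in A2780). Metallothioneins, which bind metal ions through cysteines, rose in 4 of 8 cases (5 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.603 with an estimated correlation). MT1X was higher by 2.20 ± 0.20 and MT2A by 2.10 ± 0.20. Of 7 genes listed as methylation targets, from memory of the study's published work, 6 fell (6 adjusted over the list alone; camera adjusted p = 1.31e-07, and 0.00314 with an estimated correlation). They included ARMCX2, of an armadillo repeat family (-6.74 ± 0.18), the growth factor MDK (-2.98 ± 0.15) and the collagen COL1A1 (-2.68 ± 0.20). That list was chosen in part on these samples and is not independent evidence of a direction.

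The stress response list rose in 17 of 25 genes and fell in 4, with the same numbers adjusted over the list alone (camera adjusted p = 0.00349, and adjusted p = 0.844 with an estimated correlation). CEBPB, a transcription factor of stress and inflammation, rose by 2.41 ± 0.41, while DNAJC3 (-0.78 ± 0.11) and PDIA4 (-0.87 ± 0.14), both of protein folding in the endoplasmic reticulum, fell. The median of this list was 11.03 and 10.98 log2 in CP70 replicates 1 and 3, 10.16 in replicate 2, and 9.46 to 9.59 in A2780. Without CP70 replicates 1 and 3, 1 gene of the list rose and 2 fell. Mismatch repair genes fell in 7 of 19 cases (7 adjusted over the list alone; camera adjusted p = 0.0278, and adjusted p = 0.844 with an estimated correlation). The DNA ligase LIG1 (-1.53 ± 0.32), the polymerase subunit POLD1 (-1.20 ± 0.29) and the mismatch sensors MSH6 (-0.69 ± 0.18) and MSH3 (-0.43 ± 0.11) were among them. Without CP70 replicate 2, 13 of them fell and 1 rose, and without replicates 1 and 3, 1 fell and 2 rose. MSH6 lost its call without CP70 replicate 1 or 3 (adjusted p = 0.0562 and 0.0526). The 4 probe sets of MSH6 ranged from -0.93 to 0.01, with 2 called for a fall, and the 3 of MSH3 from -0.43 to 0.09, with 1 called.

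The other lists showed no shift by camera. The numbers of genes that rose and fell follow, with those adjusted over the list alone in brackets. They were 11 and 11 of 47 interferon-stimulated genes (11 and 12), 15 and 16 of 55 matrix genes (15 and 16), 9 and 11 of 53 cell cycle genes (10 and 12) and 5 and 15 of 37 excision and crosslink repair genes (6 and 16). For apoptosis they were 8 and 8 of 37 (10 and 8), for cytokines 10 and 3 of 28 (10 and 4), for genes raised by deacetylase inhibitors 10 and 7 of 23 (10 and 7), and for protocadherins 4 and 5 of 31 (4 and 5). Cancer-testis antigens gave 1 and 2 of 30 (1 and 2), DNA methylation machinery 4 and 7 of 23 (4 and 8), histone deacetylases 3 and 3 of 18 (4 and 3) and sterol biosynthesis 2 and 5 of 18 (3 and 8). Keratins gave 3 and 1 of 14 (3 and 1), fibroblast and endothelial markers 2 and 4 of 16 (2 and 4), and germline genes 3 and 1 of 41, with 1 rise left adjusted over the list alone. The median, the mean and the camera direction differed in sign for the thiol, matrix, leukocyte, fibroblast and keratin lists. Of 14 leukocyte markers, limma called 0, with 0 at an unadjusted p under 0.05 and 0 by rank product. The matrix genes included TGFBI at 3.12 ± 0.13, the proteoglycan DCN at 3.43 ± 0.17 and SPARC at -2.32 ± 0.12. The hormone STC1 rose by 5.33 ± 0.26, the chemokine CCL20 by 3.95 ± 0.46 and the apoptosis activator PMAIP1 by 4.31 ± 0.58, while the caspase CASP4 (-2.14 ± 0.22) and the repair genes XPC (-1.20 ± 0.15) and BRIP1 (-1.41 ± 0.24) fell. The methyltransferases DNMT3A (-1.85 ± 0.22), DNMT3B (-1.05 ± 0.35) and DNMT1 (-0.40 ± 0.13) fell. HDAC1 fell by 0.74 ± 0.14, HDAC2 rose by 1.07 ± 0.08, and HDAC3 was at 0.02 ± 0.12 (limma adjusted p = 0.930). Without A2780 replicate 1 or 2 or CP70 replicate 1 or 3, DNMT1 (adjusted p = 0.0789, 0.0947, 0.101 and 0.135) and DNMT3B (0.0736, 0.0982, 0.179 and 0.164) lost their calls. DNMT3B also lost it without A2780 replicate 3 (0.0661) and was at 0.19 without CP70 replicates 1 and 3.

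In all, limma called 6174 of 19775 genes, 3174 higher and 3000 lower in CP70, and 1929 of them changed at least 2-fold. Rank product called 534 higher and 499 lower, each of them also called by limma. Without CP70 replicates 1 and 3 the limma count was 3369, and without any 1 of the 6 arrays the rank product count was 553 to 627.

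Decitabine alone was compared with untreated CP70 to find genes whose expression rises when DNA methylation is lowered. The largest rise was that of ARMCX2, from 3.64 to 10.36 log2 (6.71 ± 0.18, 105-fold), against 10.39 in A2780. Genes normally expressed in germ cells made up most of the others: MAGEA6 (6.63 ± 0.14, 99.2-fold), GCNA (6.15 ± 0.12), MAGEA12 (6.08 ± 0.16), DAZL, an RNA-binding protein of germ cells (5.71 ± 0.11, 52.4-fold), SSX1 (5.67 ± 0.20) and GTSF1 (5.67 ± 0.13), with the transketolase-like TKTL1 at 5.65 ± 0.12. Except for GCNA, the untreated levels of these 8 genes lay below 4.34 log2, so that their folds can be understated and their order is uncertain. Of 30 cancer-testis antigens, 20 rose (22 adjusted over the list alone; camera adjusted p = 5.00e-34, and 0.000434 with an estimated correlation), including MAGEA4 at 5.18 ± 0.16 and MAGEA1 at 4.87 ± 0.17. The median of the list was 4.12 to 4.17 log2 in untreated CP70 and 6.14 to 6.69 with decitabine. Germline genes outside these families rose in 20 of 41 cases and fell in 1 (23 and 1 adjusted over the list alone; camera adjusted p = 1.90e-16, and 3.70e-05 with an estimated correlation). MAEL, of the piRNA pathway, rose by 4.59 ± 0.12 and CTCFL, a testis paralog of CTCF, by 3.71 ± 0.13. MAGEA and SSX genes have near-identical copies, so that the share of each copy in a probe set's value is uncertain.

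Interferon-stimulated genes rose in 33 of 47 cases (44 adjusted over the list alone; camera adjusted p = 1.55e-31, and 0.0377 with an estimated correlation). They included the antiviral genes RSAD2 (2.72 ± 0.21), IFI44 (2.38 ± 0.21), OAS1 (2.23 ± 0.22) and MX1 (2.20 ± 0.21), and the list median went from 6.85, 6.99 and 6.94 in untreated CP70 to 8.27, 8.72 and 8.19. Cytokines and NF-kB targets rose in 13 of 28 cases (18 adjusted over the list alone; camera adjusted p = 3.57e-10, and 0.0168 with an estimated correlation), among them the chemokines CXCL8 (2.03 ± 0.28) and CCL5 (1.90 ± 0.17). In antigen presentation 5 of 30 genes rose (7 adjusted over the list alone; camera adjusted p = 0.00408, and adjusted p = 0.529 with an estimated correlation). The immunoproteasome subunit PSMB8 was at 2.37 ± 0.39 and HLA-DMA, which loads peptides on class II molecules, at 1.29 ± 0.22. Without CP70 replicates 1 and 3, 19 cancer-testis, 15 germline and 19 interferon-stimulated genes rose.

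Metallothioneins rose in 6 of 8 cases (6 adjusted over the list alone; camera adjusted p = 4.29e-11, and 0.00408 with an estimated correlation), with MT1X at 2.17 ± 0.20, MT1E at 1.93 ± 0.17 and MT2A at 1.91 ± 0.20. Keratins and squamous markers rose in 5 of 14 cases (5 adjusted over the list alone; camera adjusted p = 0.000121, and 0.00940 with an estimated correlation). KRT19 rose by 2.67 ± 0.21, the 14-3-3 protein SFN by 2.62 ± 0.18 and KRT8 by 1.37 ± 0.16. Of 23 genes commonly raised by deacetylase inhibitors, 12 rose with this methylation inhibitor (16 adjusted over the list alone; camera adjusted p = 8.29e-12, and 0.00408 with an estimated correlation), with the LIM protein CRIP1 at 4.06 ± 0.19. That list shares MT1X, MT1E and MT2A with the metallothioneins, so that the shifts of these lists are not independent. Among the 7 methylation targets, chosen in part on these samples, 5 rose (6 adjusted over the list alone; camera adjusted p = 1.44e-09, and 0.000600 with an estimated correlation). MEST went from 4.16 to 6.71 log2, against 13.29 in A2780.

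Camera also called 3 lists with few called members. Cell cycle genes lay higher (adjusted p = 0.00408, and 0.662 with an estimated correlation). Limma called 0 of these 53 over all genes and 0 adjusted over the list alone, with 15 higher and 1 lower at an unadjusted p under 0.05 and 0 by rank product. Stress response genes lay lower (2 of 25 fell, 3 adjusted over the list alone; adjusted p = 0.0272, and 0.609 with an estimated correlation), with the serine synthesis enzyme PHGDH at -0.91 ± 0.17. Sterol genes also lay lower (2 of 18 fell, 2 adjusted over the list alone; adjusted p = 0.0420, and 0.576 with an estimated correlation), with INSIG1, which retains the sterol sensor, at -0.98 ± 0.20. Both missed the threshold after a repeated quantile normalization (adjusted p = 0.0597 and 0.0708), where p53 targets passed it (adjusted p = 0.0362 against 0.0616, and 0.0448 after median centring).

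The other lists showed no shift with decitabine, and the numbers adjusted over the list alone again stand in brackets. Of the p53 targets, 5 of 31 rose (9, with 2 falls), with CDKN1A, an inhibitor of cyclin-dependent kinases, at 0.92 ± 0.21 (adjusted p = 0.0663 without decitabine replicate 2). Imprinted genes rose in 4 of 33 cases (5, with 3 falls), with PEG3 at 1.87 ± 0.18. In apoptosis 4 of 37 rose and 1 fell (4 and 1), with the death ligand TNFSF10 at 1.14 ± 0.23. Matrix genes rose in 10 of 55 cases and fell in 6 (14 and 12), with LOXL1 at 2.94 ± 0.28 and CCN2 at 2.27 ± 0.22. In DNA methylation machinery 2 of 23 rose and 2 fell (4 and 3), and TET1, a methylcytosine dioxygenase, fell by 0.79 ± 0.17. Among 18 histone deacetylases 1 rose and 3 fell (1 and 3), with HDAC4 at -0.96 ± 0.14. The rises and falls were 3 and 2 of 38 thiol genes (6 and 2), 2 and 3 of 31 protocadherins (2 and 3), 1 and 1 of 19 mismatch repair genes (3 and 1), 2 and 3 of 37 excision repair genes (2 and 4) and 3 and 2 of 16 fibroblast markers (4 and 2). Of 14 leukocyte markers 1 rose (1), TYROBP, an adaptor of immune receptors, by 1.30 ± 0.24. The median, mean and camera direction differed in sign for the protocadherin, deacetylase, leukocyte and fibroblast lists.

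The largest falls were smaller than the largest rises. MBL2, a lectin of the complement system (-2.11 ± 0.37), the transporter SLC16A4 (-2.02 ± 0.42), UST (-1.57 ± 0.26), C11orf54 (-1.57 ± 0.28) and the metalloprotease MMP16 (-1.44 ± 0.17) fell. The connexin GJA5 (-1.94 ± 0.48), the growth factor FGF19 (-1.63 ± 0.34) and PTPDC1 (-1.56 ± 0.35) also fell, but lay at 0.40, 0.68 and 0.41 against the PXD101 arrays in place of untreated CP70. GJA5 lost its call without any 1 of CP70 replicates 1 and 3 and decitabine replicates 1 to 3 (adjusted p = 0.0600 to 0.120), and PTPDC1 without CP70 replicate 1 or 3 or decitabine replicate 3 (0.0532 to 0.0678). DNMT3A rose by 0.84 ± 0.22 (adjusted p = 0.0290), which was lost without CP70 replicate 1 or 3 or decitabine replicate 3 (0.133 to 0.144). DNMT1 (0.24 ± 0.13, adjusted p = 0.279), DNMT3B (1.19 ± 0.35, 0.0534), HDAC1 (0.13 ± 0.14, 0.638), HDAC2 (-0.18 ± 0.08, 0.187) and HDAC3 (-0.11 ± 0.12, 0.678) missed the threshold.

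**Figure D2:**
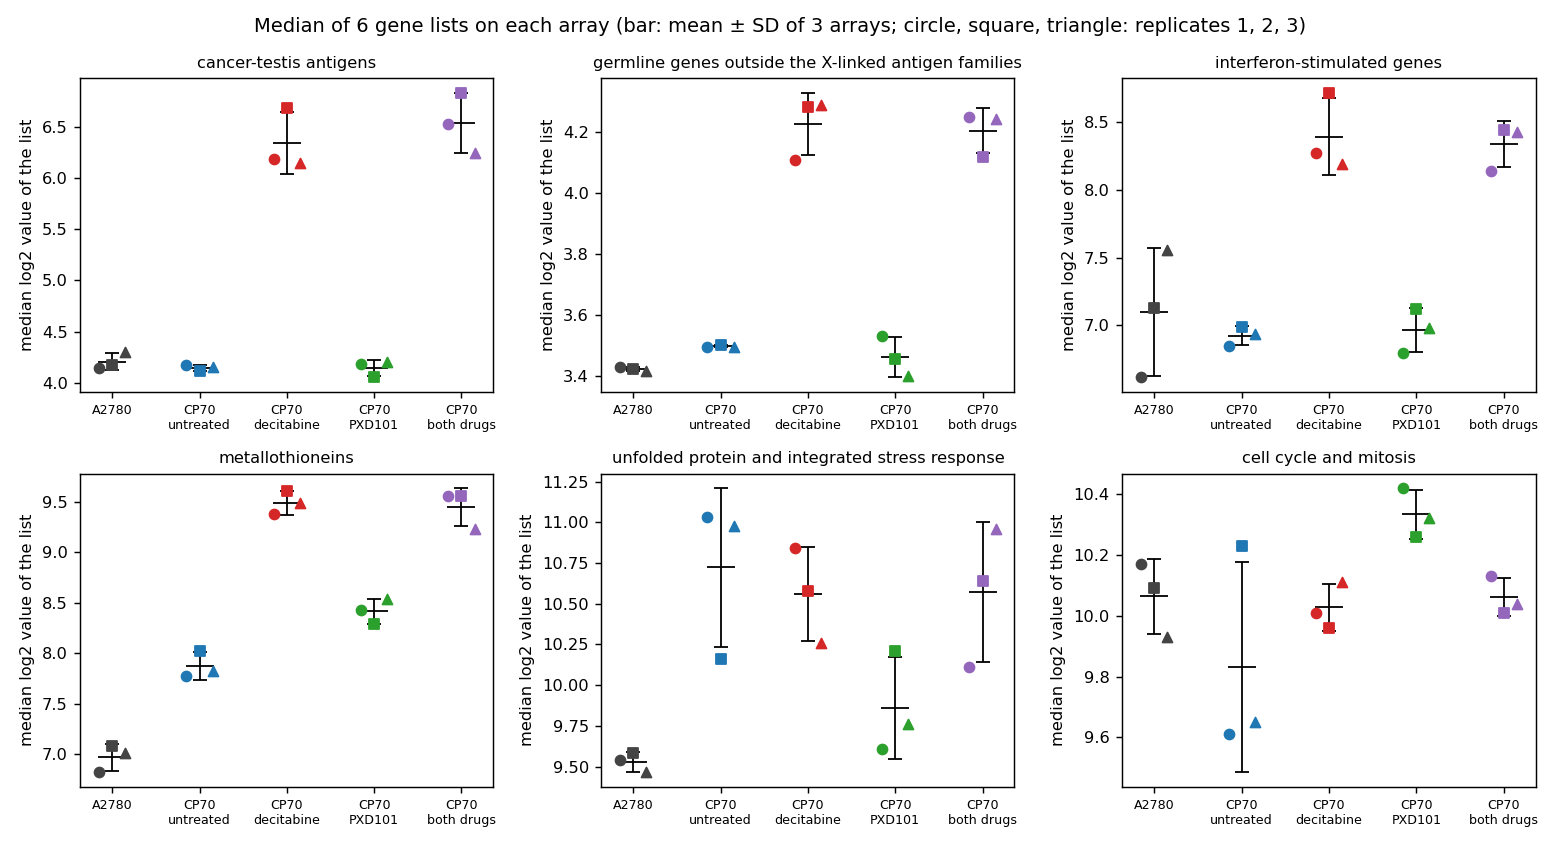
Median log2 value of 6 gene lists on each array, with a point per array and a bar for the group mean with its SD (n = 3). The cancer-testis median is 4.12 to 4.17 in untreated CP70 and 6.14 to 6.83 in the groups with decitabine, and the stress response median of CP70 replicate 2 (10.16) lies below those of replicates 1 and 3 (11.03 and 10.98).

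By limma 1583 genes changed with decitabine, 963 higher and 620 lower, 344 of them at least 2-fold. Rank product called 262 higher and 116 lower, of which 260 and 91 were also called by limma. The limma count was 849 without CP70 replicate 3, 859 without CP70 replicate 1, 997 without decitabine replicate 3 and 4673 without CP70 replicate 2. The rank product count of 378 was 194, 205 and 207 without decitabine replicates 2, 3 and 1, and 204 and 216 without CP70 replicates 3 and 1.

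Genes both lower in CP70 than in A2780 and raised by decitabine address which of the genes low in the resistant line rise with the drug. There were 288 such genes, 29.9% of those raised, and 70 of them passed 2-fold in both contrasts. ARMCX2 reached its A2780 level. GPX1 rose by 5.55 ± 0.16 (46.8-fold), the heat shock protein HSPB1 went from 5.65 to 9.71 log2 against 11.94 in A2780, and BEX1 from 5.36 to 8.16 against 12.66. The interferon-stimulated IFI27 rose by 4.96 ± 0.66, the neurofilament gene NEFL by 3.15 ± 0.18, KHDC1L by 2.83 ± 0.30, MFAP2 by 2.28 ± 0.22 and BEX4 by 2.23 ± 0.22. The lower level of IFI27 in CP70 lost its call without A2780 replicate 2 or 3 (adjusted p = 0.0655 and 0.0739).

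Independent lists of the same sizes would share 146.1 genes, and unchanged groups against the shared controls shared 19.7 on average in 20 simulations, with a highest of 29. In the opposite direction, 153 genes were raised and higher in CP70, against 154.6 for independent lists. The untreated CP70 arrays enter both contrasts and cannot be divided into parts of at least 2 arrays, so that part of the excess may come from them. The simulated groups had no drug effect, so that their small overlap does not measure that part. With the PXD101 arrays as controls for the treatment, 160 genes overlapped against 146.9 for independent lists, and in the opposite direction 352 genes were raised and higher in CP70 against 155.4. The opposite overlap then exceeded that of genes low in CP70. However, 720 genes higher in CP70 fell with PXD101 and 593 genes lower in CP70 rose, so that these controls lay lower for the former and higher for the latter. With the untreated arrays, 313 genes fell with decitabine and were higher in CP70, against 99.5 for independent lists. The overlap was 158 without CP70 replicate 3, 168 without CP70 replicate 1, 1672 without CP70 replicate 2, and 108 without replicates 1 and 3.

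**Figure D3:**
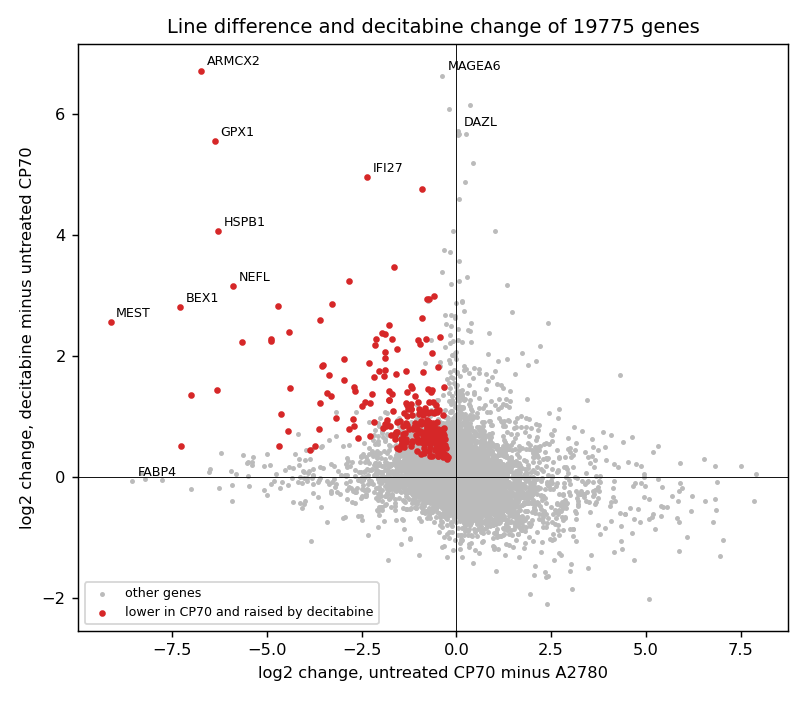
Change between the lines (untreated CP70 minus A2780, log2, horizontal axis) against the change with decitabine (log2, vertical axis) for each gene, with the 288 genes lower in CP70 and raised by decitabine in red. ARMCX2 lies at -6.74 and 6.71 and GPX1 at -6.37 and 5.55.

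PXD101 alone was compared with untreated CP70 to find genes that follow deacetylase inhibition. The largest falls were those of the calcitonin-related peptide gene CALCB (-5.20 ± 0.70), NIBAN1 (-3.79 ± 0.52), the tachykinin gene TAC1 (-3.78 ± 0.71) and the calcium-binding S100P (-3.66 ± 0.63). The stress transcription factor ATF3 (-3.54 ± 1.00), INHBE (-3.36 ± 0.73), LAMP3 (-3.33 ± 0.60) and CRNDE (-3.06 ± 0.51) followed. Of 25 stress response genes, 14 fell and 2 rose (18 and 3 adjusted over the list alone; camera adjusted p = 8.22e-08, and adjusted p = 0.621 with an estimated correlation). Asparagine synthetase ASNS fell by 2.33 ± 0.42 and the chaperone HSPA5 by 0.97 ± 0.17. ASNS was at 13.4 and 13.3 log2 in CP70 replicates 1 and 3, 11.7 in replicate 2 and 10.47 ± 0.76 (SD, n = 3) with PXD101. Cell cycle genes rose in 18 of 53 cases (33 adjusted over the list alone; camera adjusted p = 1.37e-10, and adjusted p = 0.621 with an estimated correlation). Among them were the replication genes MCM4 (1.32 ± 0.30) and CDC45 (1.28 ± 0.31) and the proliferation marker MKI67 (0.86 ± 0.21). MCM4 was at 8.40 and 8.56 in CP70 replicates 1 and 3, 9.99 in replicate 2 and 10.3 on each PXD101 array.

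Mismatch repair genes rose in 9 of 19 cases (10, with 1 fall, adjusted over the list alone) and excision and crosslink repair genes in 10 of 37, with 1 fall (19 and 3 adjusted over the list alone). Both had a camera adjusted p of 5.52e-05, and an adjusted p of 0.621 with an estimated correlation, with LIG1 at 1.18 ± 0.32, POLD1 at 1.17 ± 0.29, XPA at 0.92 ± 0.21 and BARD1 at 0.58 ± 0.11. The mismatch repair list as fixed shares PCNA, RFC3 and RFC4 with the cell cycle list, so that their shifts are not independent. Of the p53 targets, 8 of 31 fell and 2 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.663 with an estimated correlation), with the cytokine GDF15 at -2.41 ± 0.58. Metallothioneins rose in 5 of 8 cases (6 adjusted over the list alone; camera adjusted p = 0.00639, and adjusted p = 0.621 with an estimated correlation), with MT1X at 1.03 ± 0.20. Genes commonly raised by deacetylase inhibitors did not shift: 3 of 23 rose and 4 fell, and adjusted over the list alone 7 rose and 8 fell. Nor did the remaining lists, with the numbers adjusted over the list alone in brackets. Rises and falls were 2 and 1 of 30 cancer-testis antigens (2 and 1), 3 and 2 of 33 imprinted genes (3 and 2), 4 and 1 of 23 genes of DNA methylation machinery (6 and 2) and 3 and 3 of 38 thiol genes (5 and 4). They were 2 and 5 of 37 apoptosis genes (8 and 9), 3 and 7 of 55 matrix genes (5 and 12) and 1 and 4 of 18 sterol genes (5 and 4). Germline genes gave 1 and 1 of 41, with 1 fall adjusted over the list alone. Interferon-stimulated genes gave 1 and 1 of 47, lost adjusted over the list alone (7 higher and 5 lower at an unadjusted p under 0.05, and 1 and 1 by rank product). In antigen presentation 2 of 30 rose (2), of the cytokines 2 of 28 fell (2), and 1 of 14 keratins rose (1). HDAC1 and 1 of 16 fibroblast markers rose over all genes and lost the call adjusted over the list alone. The median, mean and camera direction differed in sign for the germline, imprinted and keratin lists. Limma called 0 of 31 protocadherins (2 at an unadjusted p under 0.05), 0 of 7 methylation targets (2) and 0 of 14 leukocyte markers (0), and rank product called 0 in these 3 lists.

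The largest rises were those of TMT1A (1.88 ± 0.38), the intermediate filament NES (1.85 ± 0.41), VASH2 (1.70 ± 0.37), TTC12 (1.62 ± 0.36), the imprinted PEG10 (1.58 ± 0.36), CEP128 (1.53 ± 0.37), KANK2 (1.5 ± 0.34) and ARHGEF40 (1.46 ± 0.28). DNMT3B rose by 1.37 ± 0.35, DNMT3A by 0.84 ± 0.22 and HDAC1 by 0.47 ± 0.14, while the heme oxygenase HMOX1 fell by 2.21 ± 0.50. DNMT1 (0.23 ± 0.13, adjusted p = 0.270), HDAC2 (-0.12 ± 0.08, 0.372) and HDAC3 (0.21 ± 0.12, 0.301) missed the threshold.

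Limma called 2119 genes, 1101 higher and 1018 lower, and rank product 131 higher and 229 lower, of which 124 and 216 were also called by limma. Of the 1101 genes that rose, 593 were lower in CP70 than in A2780, among them PEG10, NES, GINS2 (1.57 ± 0.44) and the antigen PRAME (0.94 ± 0.22), against 167.0 for independent lists and 18.3 for simulated unchanged groups, and part of the excess may come from the shared CP70 arrays. The simulation, which had no drug effect, does not measure that part. Most single arrays decided these calls. Limma called 0 genes without CP70 replicate 1 (3329 at an unadjusted p under 0.05, 51 by rank product), without CP70 replicate 3 (3499, and 53 by rank product), or without PXD101 replicate 1, 2 or 3 (4324, 4900 and 4780, and 120, 186 and 166 by rank product). Without CP70 replicate 2 it called 5736, with 626 by rank product, and without CP70 replicates 1 and 3 it called 0 (918 at an unadjusted p under 0.05), which also ended each of the list counts and the call of each gene named for PXD101. The overlap was then 0, against 2272 without CP70 replicate 2 and 280, 358 and 390 without A2780 replicates 2, 3 and 1.

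**Figure D4:**
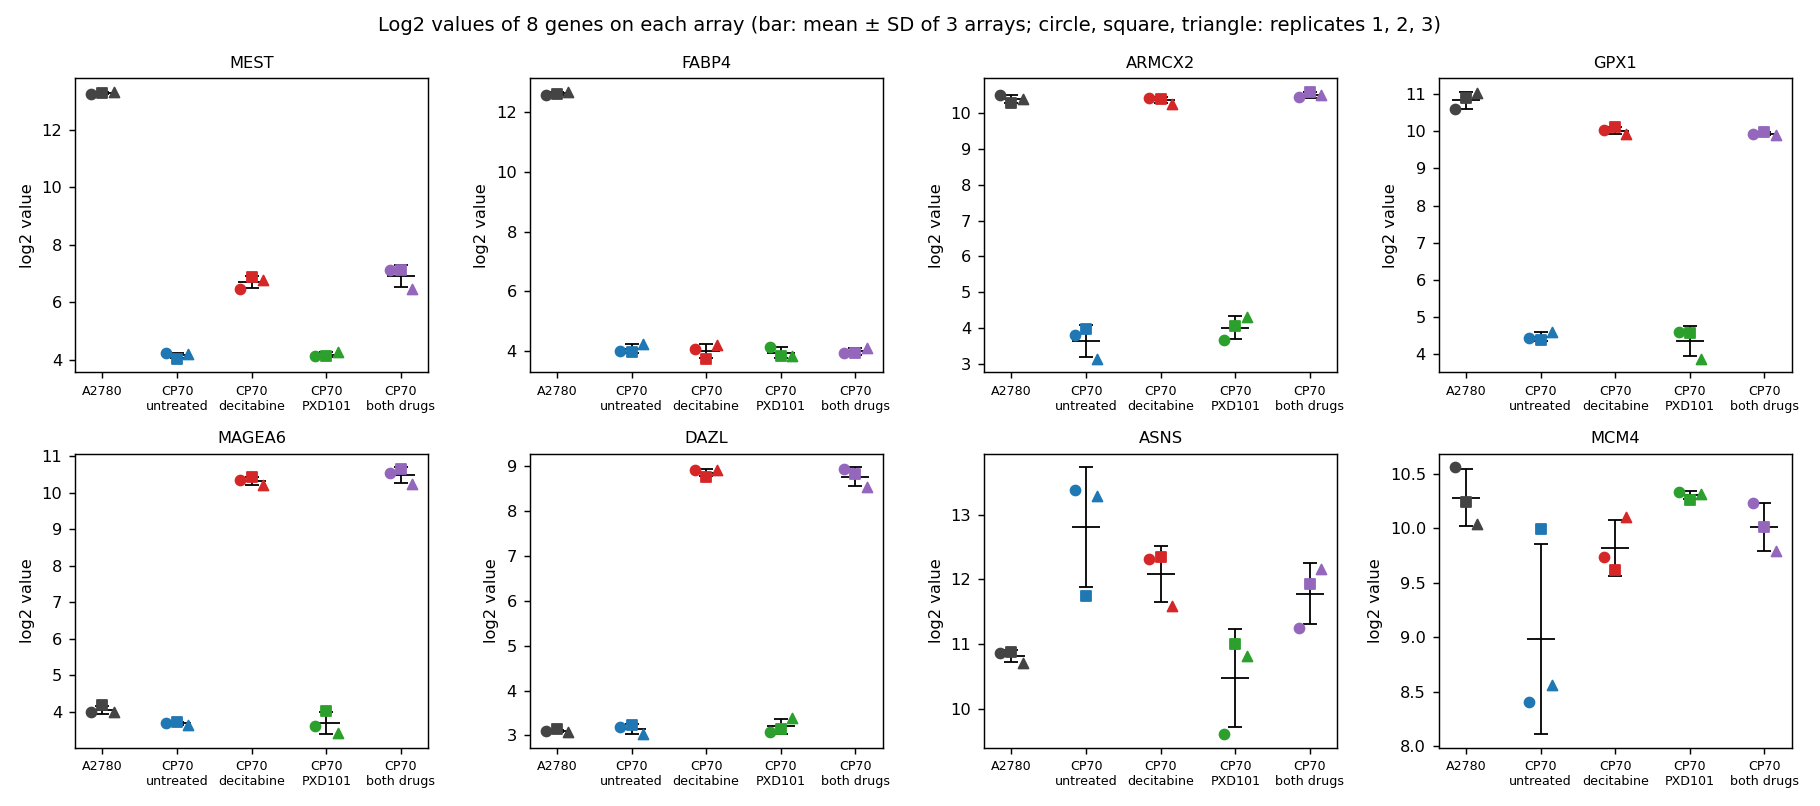
Log2 value of 8 genes on each array, with a point per array and a bar for the group mean with its SD (n = 3). ARMCX2 is near 3.64 in untreated CP70 and 10.36 with decitabine, and ASNS is lower in CP70 replicate 2 (11.7) than in replicates 1 and 3 (13.4 and 13.3).

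Both drugs together were compared with untreated CP70, with each drug alone and with the sum of the single-drug changes. Against untreated CP70 the largest rises were again ARMCX2 (6.86 ± 0.18), MAGEA6 (6.78 ± 0.14), MAGEA12 (6.21 ± 0.16), GCNA (6.05 ± 0.12), SSX1 (6.02 ± 0.20), TKTL1 (5.74 ± 0.12), GTSF1 (5.72 ± 0.13) and DAZL (5.62 ± 0.11). Cancer-testis antigens rose in 21 of 30 cases (22 adjusted over the list alone; camera adjusted p = 4.52e-35, and 0.000381 with an estimated correlation). Germline genes rose in 21 of 41 cases, with 1 fall (24 and 1 adjusted over the list alone; camera adjusted p = 1.55e-18, and 2.09e-05 with an estimated correlation). Interferon-stimulated genes rose in 32 of 47 cases (40 adjusted over the list alone; camera adjusted p = 1.09e-27, and adjusted p = 0.0527 with an estimated correlation), with RSAD2 at 2.77 ± 0.21. Of 23 genes commonly raised by deacetylase inhibitors 15 rose (16 adjusted over the list alone; camera adjusted p = 9.66e-13), with CRIP1 at 3.99 ± 0.19. The same counts were 12 of 28 for cytokines (17; 7.11e-11, with CXCL8 at 2.56 ± 0.28) and 6 of 8 for metallothioneins (6; 7.11e-11, with MT1X at 2.36 ± 0.20). They were 6 of 14 for keratins (6; 0.000394, with SFN at 3.01 ± 0.18 and KRT19 at 2.94 ± 0.21) and 5 of 7 for the methylation targets (6; 6.42e-09), chosen in part on these samples. These 5 shifts held with an estimated correlation (adjusted p = 0.00329, 0.0133, 0.00453, 0.0133 and 0.000823). Those of the deacetylase inhibitor list and the metallothioneins, which share MT1X, MT1E and MT2A, are not independent.

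Shifts upward in antigen presentation (5 of 30 rose, 5 adjusted over the list alone; adjusted p = 0.0207) and p53 targets (6 of 31 rose, 7 adjusted over the list alone; 0.0247) were lost with an estimated correlation (adjusted p = 0.498 for both). So were the downward shift of stress response genes (3 of 25 fell, 3 adjusted over the list alone; adjusted p = 0.0185, and 0.498) and the upward one of cell cycle genes (4 of 53 rose; 0.000352, and 0.503). Adjusted over the list alone limma called 0 cell cycle genes, with 18 higher and 1 lower at an unadjusted p under 0.05 and 0 by rank product. GPX1 rose by 5.47 ± 0.16, HSPB1 by 4.27 ± 0.15, MEST by 2.75 ± 0.15 and the glutamine synthetase GLUL by 2.39 ± 0.13, all 4 lower in CP70 than in A2780. Camera called no shift of the other 12 lists with both drugs, although apoptosis regulators passed after median centring (adjusted p = 0.0470 against 0.0538). Rises and falls, with those adjusted over the list alone in brackets, were 6 and 1 of 37 apoptosis genes (8 and 2), 11 and 9 of 55 matrix genes (15 and 11), 5 and 3 of 23 genes of DNA methylation machinery (7 and 3) and 3 and 2 of 38 thiol genes (3 and 2). They were 1 and 3 of 18 histone deacetylases (1 and 3), 2 and 2 of 31 protocadherins (2 and 3), 1 and 1 of 19 mismatch repair genes (4 and 2), 2 and 3 of 37 excision repair genes (3 and 3) and 3 and 2 of 16 fibroblast markers (4 and 3). Of 33 imprinted genes 5 rose (5), of 14 leukocyte markers 2 rose (3), and of 18 sterol genes 2 fell (2). Falls were led by GJA5 (-2.19 ± 0.48), SLC16A4 (-2.13 ± 0.42) and the folate enzyme ALDH1L2 (-2.08 ± 0.49), then MBL2 (-1.96 ± 0.37), COLEC12 (-1.94 ± 0.43), FGF19 (-1.93 ± 0.34), NIBAN1 (-1.92 ± 0.52) and UST (-1.78 ± 0.26). With the PXD101 arrays in place of untreated CP70, NIBAN1 was at 1.87, FGF19 at 0.38, ALDH1L2 at 0.29, GJA5 at 0.14 and COLEC12 at 0.06. NIBAN1 lost its call without CP70 replicate 1 or 3 or any array of both drugs (adjusted p = 0.0580 to 0.140), ALDH1L2 without CP70 replicate 1 or 3 or replicate 1 or 2 of both drugs (0.0630 to 0.0671), and COLEC12 and GJA5 without CP70 replicate 3 (0.0522 and 0.0558). DNMT3A (0.79 ± 0.22, adjusted p = 0.0324) and DNMT3B (1.29 ± 0.35, 0.0316) rose, and both lost the call without CP70 replicate 1 or 3 or any array of both drugs (0.0589 to 0.158). DNMT1 (0.17 ± 0.13), HDAC1 (0.10 ± 0.14), HDAC2 (-0.13 ± 0.08) and HDAC3 (-0.23 ± 0.12) missed the threshold.

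Limma called 2055 genes with both drugs, 1221 higher and 834 lower, and rank product 300 and 147, of which 297 and 129 were also called by limma. Of the genes that rose with decitabine and with both drugs, 800 were the same, and of those that fell, 470, against 59.5 and 26.2 for independent lists and 20.6 and 19.7 in simulations of unchanged groups on the shared controls. Both contrasts use the same untreated CP70 arrays, so that part of these overlaps may come from them. The simulated groups, here and for the next overlap, had no drug effect and do not measure that part. The genes lower in CP70 and raised by both drugs numbered 378, against 185.2 for independent lists and 18.95 in simulations, and 203 against 177.3 with the PXD101 arrays as controls, where 426 genes were raised and higher in CP70 against 187.6. The limma count was 1038 and 1290 without replicates 2 and 1 of both drugs, 1078 and 1113 without CP70 replicates 3 and 1, and 4917 without CP70 replicate 2. In the same order the overlap was 203, 236, 175, 181 and 1714. Rank product called 210, 241 and 260 without replicates 2, 1 and 3 of both drugs, and 240 and 272 without CP70 replicates 3 and 1.

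Against decitabine alone, 2 genes passed, both markers of pluripotent and germ cells. DPPA4 was at 3.29 log2 in untreated CP70, 4.64 with decitabine and 5.82 with both drugs (1.18 ± 0.11, limma adjusted p = 0.000429), and DPPA2 went from 5.91 to 6.77 (0.86 ± 0.11, adjusted p = 0.0170). The 3 probe sets of DPPA4 ranged from -0.065 to 1.18 in this contrast, with 1 called. At an unadjusted p under 0.05, 929 genes differed. Germline genes shifted upward (2 of 41 rose, 4 adjusted over the list alone; camera adjusted p = 0.00318, and 0.0265 with an estimated correlation). For cancer-testis antigens the camera adjusted p was 0.00532 (0.906 with an estimated correlation), and 2 of 30 passed adjusted over the list alone. Among genes above the median level, camera called 0 of 23 lists in this contrast. DPPA2 lost its call without decitabine replicate 1, 2 or 3 or without replicate 1 or 2 of both drugs (adjusted p = 0.0877 to 0.132). The count was 1 without decitabine replicate 2 or 3 or replicate 1 or 2 of both drugs.

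Against PXD101 alone, limma called 1965 genes, 1169 higher and 796 lower with both drugs. MAGEA6 (6.77 ± 0.14), ARMCX2 (6.48 ± 0.18), GCNA (6.42 ± 0.12), MAGEA12 (6.11 ± 0.16) and SSX1 (5.98 ± 0.20) rose most. The largest falls were C1orf54 (-1.61 ± 0.15), MPZL2 (-1.57 ± 0.33), the carbonic anhydrase CA14 (-1.50 ± 0.17), TET1 (-1.48 ± 0.17) and SOWAHA (-1.47 ± 0.27). In this contrast 21 of 30 cancer-testis antigens, 19 of 41 germline genes and 27 of 47 interferon-stimulated genes rose, the last with a camera adjusted p of 0.0564 with an estimated correlation. Camera called 16 of the 24 lists, 12 upward and 4 downward, and 7 with an estimated correlation. The count was 938 without replicate 2 of both drugs, and 1258 and 1307 without PXD101 replicates 1 and 2.

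The change with both drugs exceeded the sum of the single-drug changes for 3 genes: DPPA4 by 1.26 ± 0.15 (limma adjusted p = 0.0111), the antisense RNA TPT1-AS1 by 1.04 ± 0.13 (0.0111) and TRIML2, a tripartite motif family-like gene, by 0.95 ± 0.12 (0.0113). The 3 probe sets of DPPA4 ranged from -0.32 to 1.26, with 1 called. The 5 probe sets of TPT1-AS1 ranged from -0.24 to 1.04, with 2 called. TPT1-AS1 was at 5.85 log2 in untreated CP70, 5.32 with decitabine, 5.37 with PXD101 and 5.88 with both drugs, so that the combination returned it to about the untreated level. TRIML2 was at 5.01 untreated, 5.64 with decitabine, 4.62 with PXD101 and highest with both drugs. At an unadjusted p under 0.05, 3576 genes departed from the sum, and camera called 6 lists but 0 with an estimated correlation. No gene passed without decitabine replicate 2 (3631 at an unadjusted p under 0.05) or replicate 3 of both drugs (2838), and 4059 passed without CP70 replicate 2. TRIML2 also lost its call without CP70 replicate 3, PXD101 replicate 2 or replicate 1 of both drugs (adjusted p = 0.0506 to 0.0586). Exposure to PXD101 was 24 h in the combined arm and 48 h alone, and the dose was 0.1 µM in both.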

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

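Of the tests reported in this part, those on CP70 replicate 2 were chosen only after the result was seen, and the comparisons with other splits of the arrays were planned.

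The difference between the combined change and the sum of the single-drug changes passed limma's test for 3 genes: DPPA4 (1.26 log2), TPT1-AS1 (1.04, at about its untreated level with both drugs) and TRIML2 (0.95). None of the 3 kept its call without decitabine replicate 2 or replicate 3 of both drugs (adjusted p = 0.0511 to 0.0579). In 6 of 100 regroupings of the arrays, the real one included, at least 3 genes passed, and the highest count of another regrouping was 1553, so that chance is not excluded and the many calls of that regrouping point to a structure of the samples.

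Probe sets with several gene symbols or none were outside the gene-level comparisons and were tested in the same way. Of 13522 such probe sets, 1896 were called between CP70 and A2780 (741 higher and 1155 lower), 436 with decitabine (247 and 189), 403 with PXD101 (237 and 166) and 535 with both drugs (308 and 227).

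Untreated CP70 replicate 2 lay beside the PXD101 arrays and apart from CP70 replicates 1 and 3, with lower stress response and higher cell cycle values than these. A swap with a PXD101 array is argued against, since 0 of the 3 PXD101 arrays correlated better with CP70 replicates 1 and 3 than with the other PXD101 arrays. A single wrong label stays open: the root mean square distance of the array from the PXD101 mean (0.188 log2) was 0.788 of the largest distance of a PXD101 array from the mean of the other 2 (0.238), and its distance from CP70 replicates 1 and 3 was 0.445. The deviation of this array from its group mean correlated across genes with that of 1 array in each treated group: decitabine replicate 3 (0.414), replicate 1 of both drugs (0.474) and PXD101 replicate 1 (0.401), against -0.328 to -0.213 for the other 6 treated arrays and -0.068 to 0.105 in A2780. Deviations of the 3 arrays of a group sum to 0, so that a positive value forces negative ones on balance, and the negative values are no separate evidence. By the size of the positive values, against those in A2780, expression varied along the same axis inside each treated group, without PXD101 too. This leaves both explanations open. As another sign of RNA quality, the 18S 3' probe set was at 11.1 log2 in CP70 replicate 2 and 11.5 in decitabine replicate 3, against 8.13 to 9.91 on the other 13 arrays. Replicate 1 of both drugs was at 8.38 and PXD101 replicate 1 at 9.43, and RNA quality as an explanation was not tested. A culture state of CP70 replicates 1 and 3, with little lasting effect of PXD101, also stays open: over the 2119 genes called for PXD101, the change from decitabine to both drugs had a slope of 0.0347 on the PXD101 change, with the same sign in 55.6% of genes. Under a wrong label, a treated array among the controls would lower the count, which was 5736 without it. Under the culture state as candidate explanation the count of 2119 would not measure an effect of the drug alone. An effect of PXD101 that needs the absence of decitabine was not tested.

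With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the genes called by limma, 1 split of 10, the real one, gave a count as large in each comparison. The real and the highest other count were 6174 and 2 between the lines, 1583 and 1117 for decitabine, 2119 and 0 for PXD101, 2055 and 1069 for both drugs, 2 and 0 for both drugs against decitabine, and 1965 and 0 for both drugs against PXD101. By rank product they were 1033 and 41, 378 and 79, 360 and 256, and 447 and 143 for the first 4 comparisons. The other splits with 1117 and 1069 calls by limma, and with 256 by rank product for PXD101, put CP70 replicate 2 with 2 treated arrays. They thus set it apart from CP70 replicates 1 and 3, and part of the real counts may come from that difference. For gene lists called by camera, 3, 2, 1 and 2 splits gave a count as large, with 7 and 7, 12 and 14, 6 and 5, and 12 and 12 lists.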

How the results depend on the processing

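Fits without CP70 replicates 1 and 3, fits with the PXD101 arrays as controls and the list counts from both were tests chosen only after the results were seen. Of 482 pairs of a named gene and a contrast, 415 were called and 207 of these kept direction and call under every alternative run for them. A minimum of 2-fold was not run for single genes, and the median level, the PXD101 arrays as controls and the fit without CP70 replicates 1 and 3 covered only a part of the pairs. The counts of called genes and the overlaps stayed within 1.5 times of their value after repeated quantile normalization and median centring. Of 384 list counts under them, 18 moved further, each of 5 genes or fewer as reported, such as cell cycle genes raised by both drugs (4, and 1 after median centring) and imprinted genes raised by PXD101 (3, and 1 under both). Neither scaling moved the share of higher calls by over 10 percentage points. Low signal over background limits what can be said of genes below 4.34 log2, the lower quartile of all gene values. Estimated correlations kept 24 of the 61 list shifts that camera called in 168 tests. Shifts of the methylation targets, chosen in part on these samples, are among those kept. Between the lines they were the only list kept. Where no cause is named, the cause was not tested.

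Fitting only the arrays of the groups compared, which leaves fewer degrees of freedom, gave 507 genes for decitabine, 0 for PXD101 (4111 at an unadjusted p under 0.05 in limma), 834 for both drugs, 0 for both drugs against decitabine (953) and 3174 for both drugs against PXD101. The overlaps with genes lower in CP70 were then 158 for decitabine, 0 for PXD101 and 217 for both drugs.

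With the replicate block, 1198 genes were called for PXD101, the PXD101 overlap was 319 and rank product called 209, and no other count left the range of 1.5 times. The replicate numbers share no known batch: 7 of 30 pairs of groups and numbers correlated above 0.1 (range -0.38 to 0.49), and 4 of 15 arrays correlated best with their own number, so that the block is not a paired analysis.

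Among genes above the median level, which are fewer, 0 passed for both drugs against decitabine (336 of 9887 at an unadjusted p under 0.05 in limma) and 0 for the non-additive response (2525), and rank product called 511, 168, 210 and 205 in the 4 comparisons. Camera then called 2 of 23 lists between the lines (0 up and 2 down), against 7 of 24 (2 up and 5 down). It called 9, 6 and 8 with decitabine, PXD101 and both drugs, against 12, 6 and 12. With the mean of all probe sets 1 gene was non-additive, and the mismatch repair gene PMS1 turned to 0.0082 with decitabine and 0.05311 with both drugs, and SIRT5 to 0.03307 with both drugs. PMS1 has 5 probe sets, which ranged from -0.87 to 0.54 with both drugs, 1 of them called for a rise and 1 for a fall. Testing every probe set, which tests more features, gave 13104 calls between the lines, 3038 for decitabine, 3235 for PXD101, 3832 for both drugs, 3978 for both drugs against PXD101 and 8 non-additive, with overlaps of 474 for decitabine and 610 for both drugs.

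Array weights gave CP70 replicate 2 a weight of 0.158 and replicate 3 one of 5.13. The calls became 10162 between the lines, 6668 for decitabine, 8634 for PXD101, 8125 for both drugs, 5 for both drugs against decitabine, 4840 for both drugs against PXD101 and 5329 non-additive, with overlaps of 2200, 3070 and 2496. A minimum of 2-fold, which removes small changes, left 1929, 344, 378, 418, 1 and 473 genes in the first 6 comparisons and overlaps of 70, 79 and 84.

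Without CP70 replicates 1 and 3, the lone CP70 array was assumed to vary like the other groups. Calls were 3369 between the lines, 741 for decitabine, 0 for PXD101 (918 at an unadjusted p under 0.05 in limma), 865 for both drugs and 0 non-additive (975), with overlaps of 108, 0 and 116. DNMT3B turned to 0.19 between the lines, UHRF1 to -0.0542 with decitabine, and TEX15 and B4GAT1 to -0.0352 and -0.0429 with PXD101.

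With the PXD101 arrays in place of untreated CP70, the overlaps were 160 for decitabine and 203 for both drugs, while 1612 and 1965 genes were called, 728 and 921 of them as before. DNMT3B turned to 0.31 between the lines. With decitabine, FGF19 turned to 0.68, GJA5 to 0.40, PTPDC1 to 0.41, UHRF1 to -0.0566, DNMT3A to -0.0024 and DNAJC3 to 0.14. With both drugs, DNMT3A turned to -0.0510, DNMT3B to -0.0756, ALDH1L2 to 0.29, COLEC12 to 0.0623, FGF19 to 0.38, GJA5 to 0.14, NIBAN1 to 1.87 (adjusted p = 0.0338), CDC6 to -0.0531, MCM4 to -0.29 and CETN2 to -0.0296.

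Leaving out 1 array moved the calls between 4701 and 7545 for the lines, 849 and 4673 for decitabine, 0 and 5736 for PXD101, 1038 and 4917 for both drugs, 1 and 2 for both drugs against decitabine, 938 and 1666 for both drugs against PXD101, and 0 and 4059 for the non-additive response. The overlaps moved between 158 and 1672, 0 and 2272, and 175 and 1714. The highest values for decitabine, PXD101, both drugs, the non-additive response and the 3 overlaps came without CP70 replicate 2. The lowest came without CP70 replicate 3 for decitabine (849) and for the overlaps with decitabine (158) and both drugs (175), without replicate 2 of both drugs for both drugs (1038) and against PXD101 (938), and without CP70 replicate 1 or 3 or any PXD101 array for PXD101 (0, with 3329 to 4900 at an unadjusted p under 0.05). Without decitabine replicate 2 or replicate 3 of both drugs the non-additive count was 0 (3631 and 2838). Rank product moved between 553 and 627 for the lines, 194 and 545 for decitabine, 51 and 626 for PXD101, and 210 and 561 for both drugs. Among named genes, 25 lost their call without 1 array for decitabine, 29 for both drugs and 8 for the lines.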

Other observations

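The gene families in the next paragraph, the set of genes at least 16-fold lower in CP70 and the comparison of 3 lists with the PXD101 arrays were tests chosen only after the results were seen.

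Of 48 tests, 12 families in each of the 4 contrasts against an untreated line, camera called 21, and 0 with an estimated correlation, so that no family shift is secure and those below are descriptive. Of 28 HOX genes, which set body axis identity, 11 were higher and 4 lower in CP70 than in A2780 by limma (camera adjusted p = 0.0514 over the families examined, and adjusted p = 0.184 with an estimated correlation). The largest rises were HOXB7 at 4.96 ± 0.13, HOXB6 at 4.27 ± 0.15, HOXB8 at 2.89 ± 0.29 and HOXB5 at 2.66 ± 0.17, while HOXC6 was at -1.62 ± 0.13. Decitabine changed 0 of the 28 by limma. S100 genes, which encode small calcium-binding proteins, rose with decitabine in 9 of 19 cases (camera adjusted p = 7.13e-09, and adjusted p = 0.0860 with an estimated correlation), led by S100A3 at 3.47 ± 0.39, S100A2 at 1.68 ± 0.27 and S100A6 at 1.27 ± 0.21. Both drugs also raised 9 of them. Among 42 replication-dependent histone genes, 11 rose and 1 fell with decitabine (camera adjusted p = 0.000449, and adjusted p = 0.350 with an estimated correlation), and 13 rose and 1 fell with both drugs, whereas with PXD101 3 fell and the shift was downward (adjusted p = 0.00105, and 0.326 with an estimated correlation). These genes included the linker histone H1-2 at 1.63 ± 0.23 and H2BC21 at 1.27 ± 0.28 after decitabine. Ribosomal protein genes lay lower with decitabine (1 of 54 rose and 1 fell; adjusted p = 5.63e-06, and 0.299 with an estimated correlation), and 6 of 9 minichromosome maintenance genes rose with PXD101 (3.51e-05, and 0.326). Of 20 genes of the X-linked BEX, TCEAL, ARMCX and GPRASP families, 8 rose and 3 fell with decitabine (camera adjusted p = 0.00281, and adjusted p = 0.106 with an estimated correlation). Besides ARMCX2, BEX5 rose by 2.34 ± 0.15, ARMCX3 by 2.28 ± 0.24 and ARMCX1 by 0.98 ± 0.14, whereas ARMCX4 and ARMCX6 were at -0.61 and -0.54. Aminoacyl-tRNA synthetases, which charge tRNAs, were higher in CP70 than A2780 in 8 of 15 cases and lower in 1, and 7 fell with PXD101 (camera adjusted p = 2.19e-05, and adjusted p = 0.201 with an estimated correlation). Without CP70 replicates 1 and 3, 1 was higher in CP70 and limma called 0 with PXD101. The directions of the shifts given here were the same after repeated quantile normalization and median centring. The HOX shift between the lines passed the threshold after the former (adjusted p = 0.0458 at the preset correlation), and the HOX direction with PXD101, which was not called (0.974), turned.

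Cancer-testis, germline and interferon-stimulated genes rose together with decitabine. A peculiar state of the untreated CP70 arrays is argued against, since 64 of the 73 genes of these lists that rose were also called against the PXD101 arrays. Cross-hybridising probe sets stay open. Of the genes that rose and have a probe set without a suffix for shared sequence, such a probe set was called for 93.3% (14 of 15) of cancer-testis, 92.9% (13 of 14) of germline and 81.5% (22 of 27) of interferon-stimulated genes. These shares decide nothing, because for 13, 11 and 21 of the genes it was the probe set that gave the call. In the other 11 genes a different probe set without the suffix was called for 5, and 17 genes, MAGEA6, MAGEA12 and MAGEA1 among them, have only probe sets with a suffix. Direct loss of methylation at germline genes, with the interferon response as a secondary effect, is a candidate explanation that these arrays cannot test, because DNA methylation was not analysed here.

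Of the 3000 genes lower in CP70 than in A2780, 288 rose with decitabine, ARMCX2 and GPX1 foremost, and most did not. Admixture of A2780 cells is argued against: over the 70 genes at least 16-fold lower in CP70 (median line change -4.96 log2), the median change with decitabine was 0.137, with quartiles of -0.0778 and 0.501, and 18 of them rose. Whether the excess of the overlap comes from the untreated CP70 arrays that both contrasts share cannot be told, because with the PXD101 arrays as controls the ratio to independent lists was 1.09, against 1.97 with the untreated arrays. On the PXD101 arrays 593 genes lower in CP70 lay higher than on the untreated ones, against 167.0 for independent lists, which would lower the former ratio. With the PXD101 arrays, raised genes that were higher in CP70 numbered 352 against 155.4 for independent lists. That count cannot tell whether decitabine raised genes high in CP70. The PXD101 controls lay lower there, since 720 genes higher in CP70 fell with PXD101, against 163.4 for independent lists. Against untreated CP70 the raised genes higher in CP70 numbered 153, against 154.6. Of 100 regroupings of the 9 arrays, the real one included, 1 reached the overlap of 288 (highest other 137) and 1 that with both drugs of 378 (highest other 139). Nearly all of these regroupings mix the lines and so remove the line contrast, and they decide neither whether chance is excluded nor what the shared arrays add. For the overlap with PXD101 of 593, 2 of 100 regroupings were as large and the highest other, 1765, points to a structure of the samples. That overlap was also 0 without CP70 replicate 1 or 3 or any PXD101 array, and no conclusion is drawn from it. Methylation acquired in CP70 and removed by the drug may account for a part of the restored genes, which was not tested.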
